A study of Mus musculus with 6 samples.

How the data were processed

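RNA from cultured mouse peritoneal macrophages was sequenced in 6 libraries, 2 each of vehicle, LPS and SGA360+LPS. The authors deposited 1 table of whole-number read counts with 34751 transcript rows, each with a gene symbol, a RefSeq transcript and a position. Per the submitters' processing notes, TopHat2 2.0.13, HTSeq 0.5.4p3 and the mm10 build were used; the strand setting, the annotation version and the treatment of reads shared by several transcripts are not given in the sources used here. Groups and replicate numbers were taken from the labels. All sample columns matched a label.

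Counts of transcript rows were summed per symbol, which gave 24454 symbols; 5 of them have rows on more than 1 chromosome. Symbols with several rows had unusually few reads: 5639 such symbols held 1.87% of all counts and 51.0% of them were at 0 in all libraries, against 37.1% of the 18815 symbols with 1 row. Their values are uncertain, as they may cover only reads specific to an isoform, and 869 of them were among the 9389 genes tested. Positions in the table start 1 base early: start plus 1 equalled the GENCODE start of the same symbol for 52.5% of the matched genes with 1 row, and 98.27% overlapped the annotated gene, so 1-based positions are given as start plus 1.

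Genes were kept with filterByExpr of edgeR 4.0.16 (minimum count 10), scaled by TMM and tested with glmQLFit and glmQLFTest in 1 model of the 3 groups over all 6 libraries, which leaves 3 residual degrees of freedom, in R 4.3.3. Adjusted p-values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and SE is the absolute log2 fold change divided by the square root of the F statistic. CPM use TMM-scaled library sizes. For a gene with no vehicle count, the fold is a lower bound against 3 counts per library. These floors cover counting error only, since reads without molecular identifiers are not independent molecules.

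A set of 40 gene lists (pathways, cell types and target genes) was fixed before the data were examined, along with the groups, tests, alternatives and the rule for named genes. One list, of mitochondrially encoded genes, had no symbol in the table, and 2 more had no tested member, which left 37 lists of at least 3 tested members. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 37 lists, and again with an estimated correlation. For some lists that lost their call the estimate was below the preset value. With an estimate, camera also uses only the 3 residual degrees of freedom of the fit, which by itself raises p. A lost call therefore does not by itself show correlated genes. The median, mean and test of a list differed in sign for 3 lists in LPS against vehicle, 8 in SGA360+LPS against LPS and 4 in SGA360+LPS against vehicle, of which 0 were called.

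The named genes are the 8 largest rises and falls past the threshold with separated groups and a mean of at least 5 CPM, leaving out predicted genes, and up to 4 called members of each list with a mean of at least 1 CPM. Also named are up to 2 abundant members of lists with no call, and 17 genes fixed in advance whatever their result. Named outside this rule, after their values were seen, are Adgre1, Marco, Il23a, Rsad2, Phgdh, Rn45s, Lars2, genes called only in other fits (Ccl3, Ccl4, Mfsd12), genes that overlap a named one, and genes repeated from one comparison in another. Some genes that the rule names are not reported here.

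Replicates were compared by a chi-square per gene of their counts. None of the pairs agreed within sampling noise (mean 8.93 for vehicle, 3.60 for LPS and 2.97 for SGA360+LPS), so no library was counted as a duplicate. The correlation of log CPM between replicates was 0.9619 for vehicle, 0.9919 for LPS and 0.9927 for SGA360+LPS. The common biological coefficient of variation was 0.0951 over all libraries and 0.0540 for LPS and SGA360+LPS alone, so the vehicle pair widens the spread that every comparison shares. It was also 0.0540 without vehicle replicate 1 or without vehicle replicate 2. A lone vehicle library adds nothing to this estimate, so these values do not show which vehicle library differs.

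The scripts were tested on simulated counts with 200 genes changed. For LPS against vehicle (9105 genes) 52.8%, 75.3% and 84.3% of genes changed 1.5-, 2- and 4-fold were recovered, with 9 false among 154 calls. For SGA360+LPS against LPS (9199 genes) these were 55.6%, 47.7% and 93.7%, with 9 false among 139 calls, and for SGA360+LPS against vehicle (9102 genes) 36.2%, 79.4% and 87.3%, with 2 false among 136. In a simulated list raised in SGA360+LPS, the list test gave adjusted p = 8.54e-68 and called 0 other lists. Genes were drawn independently there, so this does not show how often lists of correlated genes are called falsely. The test of a common loss of the LPS rise set each induced gene against a shared fraction by its edgeR SE. It was run on simulated counts too, with the outcome not reported here.

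Alternatives were DESeq2 1.42.0 size factors and its Wald test, limma-voom, no filter, a filter of 5 CPM in 2 libraries, fits on the 2 groups compared, the replicate number as a block and each library left out in turn. Others were a threshold of 0.01, a test against a 2-fold change, other fold limits for LPS-induced genes, split LPS libraries, and camera by rank or without genes of several lists. Ranges of adjusted p given for genes include the test against a 2-fold change. A change under 2-fold gives a high p there by design. Alternatives for normalized values did not apply to counts. Chosen after seeing the data were fits on genes with 1 transcript row, on transcript rows, without Rn45s and Lars2, and without vehicle replicate 1 together with each LPS or SGA360+LPS library.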

Results

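Gene expression was measured by RNA sequencing of polyA-enriched RNA from cultured peritoneal macrophages, the phagocytes of the abdominal cavity, of wild-type C57BL6/J mice. The 6 libraries fell into 3 groups of 2: vehicle (5 h), the bacterial endotoxin LPS (10 ng/ml for 4 h), and SGA360, a ligand of the aryl hydrocarbon receptor (AHR), given at 10 µM for 1 h before the same LPS treatment. Total counts per library were 8689452 and 8874130 for vehicle, 7726973 and 9529817 for LPS, and 8045546 and 9158715 for SGA360+LPS. The labels do not say whether the libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. Levels are given in CPM, counts scaled to a common library size, as mean ± SD of n = 2 libraries, and fold changes as log2 with their standard error (SE). Vehicle replicate 1 stood apart from the other libraries: 10001 genes had a count in it, against 12282 to 12643 in the other 5, and the ribosomal RNA gene Rn45s took 4.92% of its counts, against 0.22% to 0.684% elsewhere.

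The comparison of LPS with vehicle asks what the endotoxin alone did to these macrophage cultures. Cytokine and chemokine genes were among the largest rises. Il1b, which encodes the cytokine interleukin 1 beta, went from 0.676 ± 0.957 CPM in vehicle to 1261 ± 50.7 CPM with LPS (SD, n = 2), a log2 fold change of 10.79 (SE 0.28). Its vehicle counts were 0 and 13 in replicates 1 and 2. Against a floor of 3 counts in vehicle replicate 1 alone the log2 fold change was 11.88. This is no safe lower bound, as it rests on a 0 in the library that stood apart. With 1 library left out the fitted value went as low as 9.87. The neutrophil-attracting chemokine genes Cxcl3 and Cxcl2 rose by 9.85 (SE 0.14) and 8.76 (SE 0.11). Irg1, which encodes the enzyme that makes itaconate, reached 4629 ± 207 CPM from 10.3 ± 0.29 CPM. Il12b, encoding a subunit shared by interleukins 12 and 23, rose by 8.15, the guanylate-binding protein gene Gbp5 by 7.09 and the cystine transporter gene Slc7a11 by 6.71. Tmem132e had no count in either vehicle library and averaged 9.67 CPM with LPS, at least 29.9-fold higher against a floor of 3 counts per library.

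Genes that fell most included Slc46a3, a member of a solute carrier family, which went from 33.5 ± 6.62 CPM to 1.48 ± 0.544 CPM (log2 fold change −4.52, SE 0.29). Abcg3 (−3.65), Nat8l (−3.61), the chemokine receptor genes Cxcr4 (−3.58) and Cx3cr1 (−3.48), the ubiquitin ligase gene Fbxo32 (−3.52), the peroxisomal transporter gene Abcd2 (−3.50) and Rgs2 (−3.37), a regulator of G protein signalling, followed. In all, 3413 of 9389 genes tested changed by edgeR's quasi-likelihood test with a Benjamini-Hochberg adjusted p under 0.05: 1820 rose and 1593 fell, of which 652 and 567 did so by more than 2-fold (1225 and 1096 without vehicle replicate 2). Without vehicle replicate 1 the count was 3998, and 3149 of the 3412 changed genes still tested kept their call and direction, while 0 changed sign. The count was 5494 without vehicle replicate 2, 2217 without LPS replicate 1, 2091 without LPS replicate 2, 2216 at a threshold of 0.01 and 604 when tested against a 2-fold change.

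In the mm10 build, Il1b (NM_008361 in the deposited table) spans chromosome 2 from 129364578 to 129371139 on the minus strand, and Cxcl3 (NM_203320) chromosome 5 from 90786101 to 90788093 on the plus strand. Il12b (NM_001303244) spans chromosome 11 from 44400063 to 44414677 on the plus strand, and Slc46a3 (NM_027872) chromosome 5 from 147878441 to 147894802 on the minus strand. Each is annotated as a protein-coding gene, and its count is of reads assigned to the transcript. The span of Il1b overlaps that of the antisense gene Il1bos, that of Cxcl10 overlaps Art3, that of Lpcat2 overlaps Capns2 and that of Tiparp overlaps 4931440P22Rik, while microRNA genes lie within the spans of Gbp2, Nfkbia, Nlrc5 and Scd2. Whether strand was used in counting is not given in the sources used here, so reads of such partners cannot be told apart.

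Of the fixed list of proinflammatory cytokines, 13 of 14 tested members rose with LPS and 1 had no call (13 also when adjusted over the list alone). The fitted median log2 fold change of this list was 6.40, or 3.52 when its 3 members without a vehicle count were set to their lower bound. Those were Csf2, encoding the growth factor GM-CSF, at least 8.91-fold higher, Il23a, encoding the interleukin 23 subunit p19, at least 4.73-fold, and Tnf, encoding tumour necrosis factor, at least 6.50-fold. Tnf has 2 transcript rows and only 16 and 19 counts in the LPS libraries, so its value is uncertain. Of 19 chemokine genes, 16 rose, 1 fell and 2 had no call, the same numbers when adjusted over the list alone: Ccl2, a monocyte attractant, went from 57.8 ± 1.69 to 577 ± 11 CPM, Cxcl10, an interferon-inducible T cell attractant, rose by 6.00 and Ccl5 by 5.97. All 20 tested inflammatory effectors rose (20 adjusted over the list alone), with Ptges (5.91) and Ptgs2 (5.44), both enzymes of prostaglandin E2 synthesis, and the iron-sequestering lipocalin gene Lcn2 (5.62) among them. Saa3, an acute-phase gene, was already at 2550 ± 284 CPM in vehicle and rose to 9668 ± 830 CPM. Among the NF-kB family and its feedback genes, 17 of 18 rose (17 adjusted over the list alone), including Tnip3 (4.43), Traf1 (4.19) and Nfkbia (3.42), which encodes the inhibitor IkB alpha. With camera, adjusted p was 4.77e-28 for the cytokines, 9.24e-61 for the chemokines, 1.54e-48 for the effectors and 4.02e-35 for the NF-kB list, and each of these 4 kept its call with an estimated correlation (adjusted p = 0.014 with an estimated correlation for each).

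All 23 tested interferon-stimulated genes rose with LPS (23 adjusted over the list alone; median log2 fold change 3.03), among them Ifit1 (6.30), Isg15 (5.69), a ubiquitin-like modifier, and Gbp2 (5.07). The camera call of this list (adjusted p = 3.80e-56) was lost with an estimated correlation (adjusted p = 0.0679 with an estimated correlation). All 11 MHC class I antigen presentation genes rose (11 adjusted over the list alone; camera adjusted p = 2.19e-09). Of 14 apoptosis and cell survival genes 9 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 4.21e-10), and of 20 NRF2 target genes 12 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 1.13e-09). These 3 lists also lost their call, with adjusted p = 0.0679 with an estimated correlation for each. Over all alternatives the lowest adjusted p was 2.25e-77 for the interferon-stimulated genes and 2.81e-10, 1.89e-11 and 6.36e-12 for these 3. Examples were Nlrc5 (2.07), a transactivator of MHC class I genes, and the peptide transporter gene Tap2 (1.69), the survival gene Bcl2a1a (4.58), which has near-identical paralogs and is uncertain for that reason, and the antioxidant gene Srxn1 (1.80).

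Pattern recognition receptors other than TLR4 showed 11 rises and 2 falls among 16 members (11 and 3 adjusted over the list alone), led by the C-type lectin gene Clec4e (6.07), the bacterial sensor Nod2 (4.32), the inflammasome sensor Nlrp3 (4.29) and Tlr2 (3.27). In the TLR4 signalling list 7 of 12 rose and 1 fell (8 and 2 adjusted over the list alone), with the LPS co-receptor gene Cd14 at 2.98, the kinase gene Ikbke at 1.89 and the adaptor gene Myd88 at 1.18. The camera adjusted p was 8.01e-11 and 0.000274, with adjusted p = 0.0897 and adjusted p = 0.27 with an estimated correlation. The anti-inflammatory and alternative activation list was the 1 list called downward (adjusted p = 0.0098, and adjusted p = 0.308 with an estimated correlation). Of its 13 members 6 fell, among them Arg1, encoding arginase 1, from 785 ± 2.64 to 163 ± 5.89 CPM, the efferocytosis receptor gene Mertk (−2.14) and its ligand gene Gas6 (−1.97). Another 4 rose, including the transglutaminase gene Tgm2 (1.71). The counts were 4 and 6 as well when adjusted over the list alone.

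Of 7 tested AHR target genes, 3 rose with LPS (3 adjusted over the list alone; camera adjusted p = 0.0098, and adjusted p = 0.454 with an estimated correlation). Cyp1b1, a cytochrome P450 gene induced through AHR, went from 330 ± 7.56 to 725 ± 44.0 CPM, a log2 fold change of 1.14 (SE 0.07), and Lpcat2, a lysophospholipid acyltransferase gene, rose by 2.12. Tiparp, a canonical AHR target, stood at 0.24 (SE 0.14; adjusted p = 0.215). Without vehicle replicate 1 it was at 0.41 (adjusted p = 0.0192, the lowest of a range up to 1 over the alternatives). Nqo1 stood at 0.69 (SE 0.33; adjusted p = 0.138), and without vehicle replicate 2 at 1.08 (adjusted p = 0.00863, the lowest of a range up to 1). Ahr, Ahrr and Cyp1a1 had 0 counts in all 6 libraries, Il6 had 1 count in each of the 4 LPS-treated libraries, and Nos2 had 6 and 8 counts with LPS. Each of these 5 genes has 2 or 3 transcript rows, and the 5639 symbols with several rows held only 1.87% of all counts, so no statement on their expression is made. Il10 had 14 and 3 counts in vehicle and 4 and 4 with LPS, and Ifnb1 had 0 counts in these 4 libraries; neither was detectable well enough to be tested.

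Glycolysis and HIF-1 targets rose in 7 of 14 cases and fell in 1 (7 and 1 adjusted over the list alone), with the glucose transporter gene Slc2a1 at 1.33 and the hexokinase gene Hk2 at 1.18. Integrated stress response genes rose in 6 of 10 cases (6 adjusted over the list alone), including Asns (0.95), which encodes asparagine synthetase, and Nupr1 (1.13). Camera gave adjusted p = 0.0335 for each, against adjusted p = 0.516 and adjusted p = 0.27 with an estimated correlation. By rank the calls of the TLR4, AHR target and glycolysis lists (adjusted p = 0.0575 each) and of the anti-inflammatory list (0.387, and 0.443 without genes of several lists) were lost. The glycolysis call was lost without vehicle replicate 1 (0.0514) and with a filter of 5 CPM (0.0812). That of the integrated stress response was lost with that filter (0.0684) and without vehicle replicate 2 (0.115), LPS replicate 1 (0.0658) or 2 (0.0669), or SGA360+LPS replicate 1 (0.0511) or 2 (0.0525). Over all alternatives adjusted p ran from 6.64e-05 to 0.27 for TLR4, 0.00302 to 0.454 for AHR targets, 0.00715 to 0.443 for anti-inflammatory, 0.0251 to 0.516 for glycolysis and 0.0251 to 0.27 for stress response genes. Macrophage identity genes went both ways, with 3 rises and 7 falls among 14 (3 and 7 adjusted over the list alone; camera adjusted p = 0.189). The Fc receptor gene Fcgr1 was lower (−2.39), and Adgre1, which encodes the surface marker F4/80, rose by 1.30. Among markers of other cells, all 10 tested mesothelial and all 6 tested fibroblast markers lay below 0 with LPS (medians −0.48 and −0.44). Of these 4 and 1 fell (4 and 1 adjusted over the list alone), and camera adjusted p was 0.117 and 0.436. By rank the mesothelial list was called (adjusted p = 0.0104, in a range from 0.0104 to 0.454).

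The comparison of SGA360+LPS with LPS alone asks what the AHR ligand did under the endotoxin stimulus. The labels give no vehicle pretreatment for the LPS group, so a difference in solvent or handling is not excluded. In all, 7 genes were lower and 0 were higher. Il1b went from 1261 ± 50.7 CPM with LPS to 613 ± 57.0 CPM with SGA360+LPS (SD, n = 2), a log2 fold change of −1.04 (SE 0.14; adjusted p = 0.0393), against 0.676 ± 0.957 CPM in vehicle. Ptgs2, which encodes the inducible cyclooxygenase COX-2, went from 259 ± 8.03 to 132 ± 5.69 CPM (−0.97, SE 0.08; adjusted p = 0.00223). Il1a, encoding interleukin 1 alpha, went from 756 ± 52.8 to 404 ± 10.2 CPM (−0.90, SE 0.10; adjusted p = 0.00961). Cxcl1 and Cxcl2, both encoding neutrophil attractants, fell by 0.67 (SE 0.09; adjusted p = 0.0281) and 0.62 (SE 0.07; adjusted p = 0.00961). Ier3, an NF-kB-inducible early response gene, fell by 0.67 (SE 0.08; adjusted p = 0.0174). Cyp1b1, the AHR target, fell from 725 ± 44.0 to 474 ± 1.77 CPM (−0.61, SE 0.07; adjusted p = 0.00961), with 330 ± 7.56 CPM in vehicle. For each of the 7 genes both SGA360+LPS libraries lay below both LPS libraries.

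**Figure D1:**
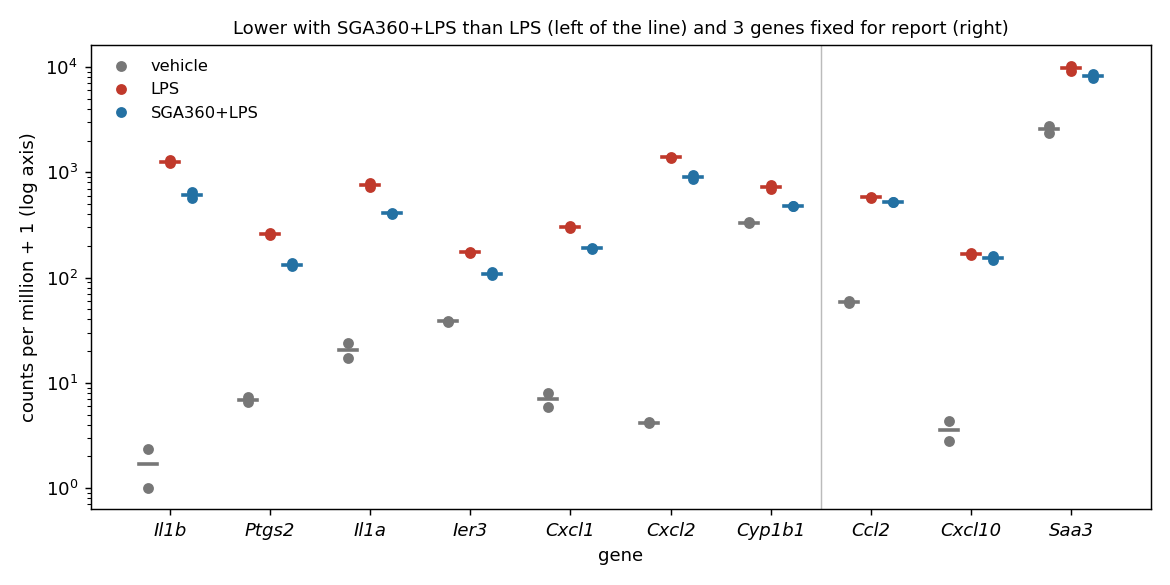
CPM plus 1 (log axis) of the 7 genes lower with SGA360+LPS than with LPS and, right of the line, 3 genes fixed for report; each point is a library and each bar a group mean of 2 libraries. Il1b averages 1261 CPM with LPS and 613 CPM with SGA360+LPS, while the points for Ccl2, Cxcl10 and Saa3 with SGA360 lie close to those with LPS alone on this log axis. Other genes fixed for report are not drawn, among them Il12b (log2 fold change −0.51, no call).

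In the mm10 build these genes lie, as the deposited table gives their transcripts, on chromosome 1 from 150100031 to 150108234 (Ptgs2, NM_011198, plus strand), and chromosome 2 from 129299610 to 129309972 (Il1a, NM_010554, minus strand). On chromosome 5 they span from 90891245 to 90893115 (Cxcl1, NM_008176, plus strand) and from 90903899 to 90905938 (Cxcl2, NM_009140, plus strand), and on chromosome 17 from 35821713 to 35822911 (Ier3, NM_133662, plus strand) and from 79706953 to 79715041 (Cyp1b1, NM_009994, minus strand). All are annotated as protein-coding. The span of Il1a overlaps that of Gm14023.

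The calls are from edgeR's quasi-likelihood test over the same 9389 genes, in which 276 genes had an unadjusted p under 0.05, where chance gives 469. In the fit on the LPS and SGA360+LPS libraries alone, 821 of 9094 genes did. The vehicle pair widens the shared spread (common biological coefficient of variation 0.0951, against 0.0540 for these 2 groups alone). The low count of 276 therefore does not show an absence of change. For the count of 0 higher genes, DESeq2 gave 1, limma-voom 0, the fit with no filter 2, and the fits without vehicle replicate 1 or 2 gave 2 and 3. With 1 library left out, 3 genes were called without LPS replicate 1, and 0 without LPS replicate 2, SGA360+LPS replicate 1 or SGA360+LPS replicate 2, while the folds stayed from −1.14 to −0.95 for Il1b and from −1.01 to −0.93 for Ptgs2. Without vehicle replicate 1 or 2, 15 and 16 genes were called, including all 7 in both cases. In fits chosen after the data were seen, vehicle replicate 1 was left out together with LPS replicate 1, LPS replicate 2, SGA360+LPS replicate 1 or SGA360+LPS replicate 2; these called 111, 63, 21 and 55 genes, each including all 7 lower ones, and of these calls 45, 25, 2 and 30 were higher. In a fit on the LPS and SGA360+LPS libraries alone, 12 genes were called, which added the lower chemokine genes Ccl3, Ccl4 and Cxcl3, the lower Il12b and the higher Mfsd12 to the 7. The test against a 2-fold change called 0 genes. Il1b was not called by DESeq2 (adjusted p = 1, in a range from 8.91e-41 to 1 over its alternatives) or with the replicate number as a block (0.0517). Cxcl1 was not called with the block (0.0517, in a range from 5.44e-14 to 1). Such ranges for genes include the test against a 2-fold change, so their upper end is not only about calls against no change.

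Other genes fixed for report did not pass the test between these groups. Il12b was at 218 ± 1.90 CPM with LPS and 154 ± 2.40 CPM with SGA360+LPS (−0.51, SE 0.08; adjusted p = 0.0998). It was called by DESeq2 (0.00161), limma-voom (0.0402), and without vehicle replicate 1 (0.000973) or 2 (0.000802), in a range from 9.44e-07 to 1. Ccl2 was at 577 ± 11 and 524 ± 1.75 CPM (−0.14, SE 0.06). Cxcl10 was at 167 ± 5.49 and 152 ± 9.08 CPM (−0.13, SE 0.11), and Saa3 at 9668 ± 830 and 8249 ± 575 CPM (−0.23, SE 0.09). The AHR targets Tiparp (−0.04, SE 0.14) and Nqo1 (−0.08, SE 0.32) likewise had no call; both had an adjusted p of 1, as did Ccl2, Cxcl10 and Saa3. Their sign turned without LPS replicate 2 (0.136 and 0.28) and without SGA360+LPS replicate 1 (0.082 and 0.001). Tnf had 8 and 15 counts with SGA360+LPS against 16 and 19 with LPS, too few for a statement. A group given SGA360 without LPS was not analysed here.

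By the fixed lists, 2 of 14 proinflammatory cytokines were lower and 12 had no call (3 lower when adjusted over the list alone); 12 of the 14 lay below 0, with a median of −0.46. Of 19 chemokine genes 2 were lower and 17 had no call (5 lower adjusted over the list alone), and 18 lay below 0 (median −0.26). Of 20 inflammatory effectors 1 was lower and 19 had no call (1 adjusted over the list alone), and 19 lay below 0 (median −0.18). Camera adjusted p was 1.02e-28, 1.24e-21 and 1.72e-13 for these 3 lists, and adjusted p = 0.0435 with an estimated correlation for each. The NF-kB list (1 of 18 lower, 2 adjusted over the list alone; median −0.19) had a camera adjusted p of 1.25e-12, and adjusted p = 0.121 with an estimated correlation. The AHR target list (1 of 7 lower, Cyp1b1, and 1 adjusted over the list alone; median −0.14) had 1.58e-05, and adjusted p = 0.333 with an estimated correlation. Immediate early genes (0 of 14 with a call, 0 adjusted over the list alone; median −0.12) had an adjusted p of 0.0067, and adjusted p = 0.386 with an estimated correlation. By rank the AHR target (0.0993) and immediate early (0.0795) calls were lost, and the latter also without LPS replicate 1 (0.063) and SGA360+LPS replicate 2 (0.145). Adjusted p ran over the alternatives from 1.86e-14 to 0.121 for NF-kB, 1.31e-07 to 0.333 for AHR target and 0.000937 to 0.386 for immediate early genes.

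The 23 interferon-stimulated genes shifted the other way as a list: 20 lay above 0 with a median of 0.185 (camera adjusted p = 3.78e-08), although no member had a call over all genes and 1, Rsad2, was higher when adjusted over the list alone. The call of the list was lost with an estimated correlation of its genes (adjusted p = 0.456 with an estimated correlation) and without LPS replicate 1 (adjusted p = 0.063), in a range from 7.77e-17 to 0.456. Rsad2, which encodes the antiviral enzyme viperin and was chosen after its values were seen, was at 363 ± 25.1 CPM with LPS and 476 ± 49.5 CPM with SGA360+LPS (0.39, SE 0.09). Its adjusted p was 1, against 0.0313 by DESeq2 and 0.047 without vehicle replicate 2, in a range from 1.63e-05 to 1. The most abundant members, Gbp2 (−0.08, SE 0.10) and Gbp5 (−0.11, SE 0.07), had no call. Upward shifts without any called member were also found for the integrated stress response (median 0.18; adjusted p = 0.000223), fatty acid synthesis (0.09; 0.00383), NRF2 target (0.07; 0.0132) and cholesterol biosynthesis (0.07; 0.0397) lists. With an estimated correlation these 4 lists gave adjusted p = 0.174, 0.248, 0.386 and 0.488, each the highest over the alternatives, the lowest being 0.000199, 0.00147, 0.00391 and 0.0267. The estimates were −0.046, −0.044, 0.038 and 0.07. Those of the stress response and fatty acid lists lie below the preset 0.01, so stronger correlation of genes is not why these calls were lost. The test with an estimate also had only the 3 residual degrees of freedom of the fit. Calls were also lost without LPS replicate 1 (NRF2 0.161, cholesterol 0.121), LPS replicate 2 (cholesterol 0.0779) and SGA360+LPS replicate 2 (NRF2 0.175, cholesterol 0.136, fatty acid 0.0836), and for cholesterol with a filter of 5 CPM (0.0883) and with genes of 1 transcript row (0.0999). Adjusted over the list alone, 1 stress response gene and 1 fatty acid synthesis gene were higher. Phgdh, a serine synthesis gene chosen after its values were seen, was at 240 ± 3.76 and 284 ± 1.03 CPM (0.24, SE 0.07) and the fatty acid synthase gene Fasn at 398 ± 17.2 and 475 ± 1.96 CPM (0.26, SE 0.07). For the NRF2 and cholesterol lists that count was 0. The desaturase gene Scd2 was at 819 ± 16.1 and 920 ± 3.04 CPM (0.17, SE 0.06), and none of these 3 had a call over all genes.

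**Figure D2:**
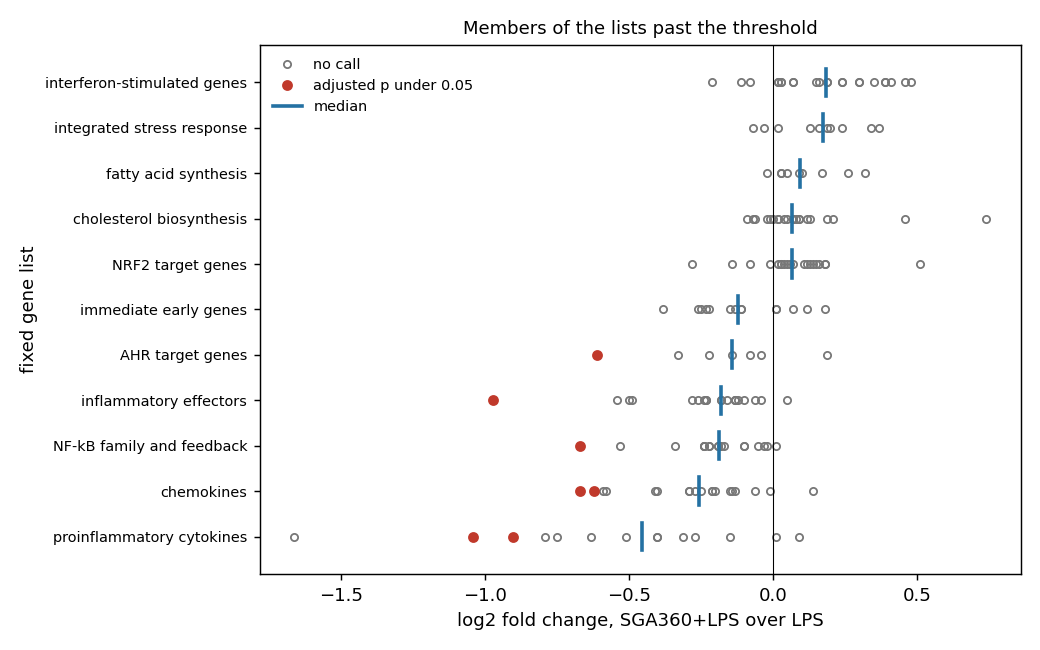
Log2 fold change of SGA360+LPS over LPS for each tested member (points) of the 11 fixed lists past the camera threshold; filled points are genes with adjusted p under 0.05 and blue bars are list medians. Medians run from −0.46 for proinflammatory cytokines to 0.185 for interferon-stimulated genes; 3 of the 11 lists kept their call with an estimated correlation.

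Whether SGA360 moved the genes that LPS had moved was asked by overlapping the calls of both comparisons. All 7 genes lower with SGA360 were among the 652 genes induced more than 2-fold by LPS, where independent lists would share 0.486. As 0 genes were called higher, an overlap with the 567 repressed genes could not be seen. Both comparisons use the same LPS libraries: with unchanged groups, 50 simulated draws gave a mean overlap of 0.02 genes, but called only 1.46 and 0.18 genes on average, so this value does not show what sharing adds where many genes change. The covariance of the log2 fold changes over genes was −0.0702, against −0.0274 in the simulation, a difference of −0.0428. Pearson's correlation over genes, which are not independent replicates, was −0.259, against −0.406 in the simulation (−0.441 to −0.350). Of the LPS-induced genes 68.3% lay below 0 with SGA360, where the simulation gave 71.4% for the genes that rose most by chance. The simulation holds no LPS effect, so its fold changes with LPS are noise alone. Its correlation and its share are therefore no chance level for genes that LPS did move. With LPS replicate 1 used against vehicle and replicate 2 against SGA360+LPS this share was 70.8%, and with the reverse 64.0%, with no shared library. In the former split 1 gene was called lower with SGA360 and overlapped, and in the reverse 0 were called, too few to weigh the overlap. Part of the excess may come from the shared libraries.

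**Figure D3:**
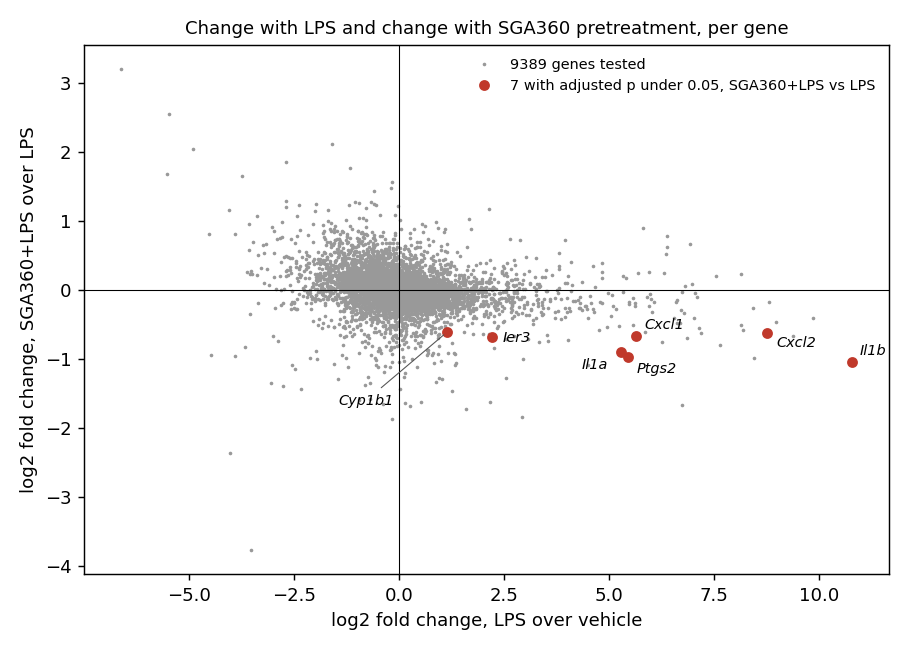
Log2 fold change with LPS over vehicle (x axis) and with SGA360+LPS over LPS (y axis) for the 9389 genes tested (grey points) and the 7 genes with adjusted p under 0.05 in the second comparison (red points, named). All 7 lie at positive values on the x axis, from 1.14 for Cyp1b1 to 10.79 for Il1b, and at negative values on the y axis; both axes share the LPS libraries.

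The comparison of SGA360+LPS with vehicle gives the combined change against untreated cells. The log2 fold change over vehicle was 9.74 for Il1b, 8.14 for Cxcl2, 4.47 for Ptgs2 and 4.38 for Il1a, and 0.52 for Cyp1b1. Of the lists, 11 of 14 proinflammatory cytokines, 15 of 19 chemokine genes, 22 of 23 interferon-stimulated genes and 19 of 20 inflammatory effectors rose (12, 15, 23 and 20 adjusted over the list alone), and 1 chemokine gene fell (2 adjusted over the list alone). Camera adjusted p was 3.19e-24, 3.63e-58, 3.51e-67 and 4.63e-46, and with an estimated correlation adjusted p = 0.0192, 0.018, 0.0507 and 0.018, so the call of the interferon-stimulated genes was lost. Arg1 (−2.24) and Mertk (−1.96) fell, as they did with LPS alone.

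In this comparison 3107 of 9389 genes changed by edgeR's quasi-likelihood test, 1678 upward and 1429 downward. Of these, 1542 rose and 1290 fell in both comparisons with vehicle and 0 went opposite ways; independent lists would share 325 and 242, and simulated unchanged groups, with 1.46 calls on average for LPS against vehicle, shared 0.5 and 0.34, too few calls to show what sharing adds. The covariance of both sets of fold changes was 1.01, against 0.0571 from shared vehicle libraries alone, a difference of 0.951; part of the excess in overlap may come from those libraries. The count of changed genes was 3572 without vehicle replicate 1, 5315 without vehicle replicate 2, and 1831 and 1872 without SGA360+LPS replicate 1 and 2.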

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

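The fits without vehicle replicate 1 together with another library, on genes with 1 transcript row, on transcript rows and without Rn45s and Lars2 were chosen after the data were seen. DESeq2 size factors, limma-voom, the filter of 5 CPM and the last 3 of those fits left every count of changed genes within 1.5 times of the main one. The counts of called lists also stayed within it in those of these fits where lists were run, which leaves out limma-voom and transcript rows. For SGA360+LPS against LPS, where 7 genes were called, DESeq2 called 11, no filter 17, the 2 groups alone 12, a threshold of 0.01 4 and the test against 2-fold 0. Leaving out 1 library gave 0 (LPS replicate 2, SGA360+LPS replicate 1 or 2) to 16 (vehicle replicate 2), with 15 without vehicle replicate 1 and 3 without LPS replicate 1. The folds of the 7 genes kept their sign in all 6 of these fits (Il1b −1.14 to −0.95, Ptgs2 −1.01 to −0.93, Cyp1b1 −0.68 to −0.55). With vehicle replicate 1 also left out, leaving out LPS replicate 1, LPS replicate 2, SGA360+LPS replicate 1 or SGA360+LPS replicate 2 gave 111, 63, 21 and 55 calls, each including all 7, of which 45, 25, 2 and 30 were higher. These fits have few residual degrees of freedom, and in all such fits a lone library is assumed to vary like the other groups. LPS against vehicle gave 2216 genes at 0.01, 604 against 2-fold, and 2091 to 5494 with 1 library left out; SGA360+LPS against vehicle gave 2050, 539, and 1831 to 5315. The overlap of LPS-induced genes lower with SGA360 was 14 with no filter, 11 with the 2 groups alone, 4 at 0.01, 1 and 0 with the LPS libraries split, and 0 to 13 with 1 library left out. LPS-repressed genes higher with SGA360 numbered 1 with no filter, 1 with the 2 groups alone, and 0 to 1 with 1 library left out. With an estimated correlation, 4 lists were called for LPS against vehicle and 3 for SGA360+LPS against LPS; the rank version gave 12 and 9. Tiparp, with no call between SGA360+LPS and LPS, ranged from −0.188 to 0.136, and Nqo1 from −0.361 to 0.28, with 1 library left out. Apart from fewer samples, a stricter threshold and the spread of the vehicle pair (common biological coefficient of variation 0.0951 with both and 0.0540 without either one), the cause was not tested.

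The replicate numbers were not taken to pair the samples, as no label ties them to a shared animal or batch. The deviations of replicate 1 correlated at −0.007 (vehicle and LPS), 0.015 (vehicle and SGA360+LPS) and 0.163 (LPS and SGA360+LPS), and Rn45s and Lars2 took a larger share in replicate 1 than in replicate 2 of each group, so a link between same-numbered libraries is not excluded. With the replicate block, 3434, 5 and 3136 genes were called for LPS against vehicle, SGA360+LPS against LPS and SGA360+LPS against vehicle.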

Other observations

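The tests on ribosomal RNA depth, removed low counts, an equally weaker LPS response, the macrophage share and the shared LPS libraries, with their bounds, were chosen after the results were seen. The test on copied molecules was not. All 10 tested mesothelial markers and all 6 fibroblast markers lay below 0 with LPS (medians −0.48 and −0.44). Over all libraries the tested fibroblast markers had a median level of 381 CPM and the mesothelial markers 33 CPM, against 765 CPM for macrophage identity genes. Cells other than macrophages may therefore have contributed to the changes given here, and these counts cannot assign a change to a cell type. Of the mesothelial markers 4 fell, led by Lrrn4 from 167 ± 14.1 to 81.2 ± 9.90 CPM (SD, n = 2) and Upk1b from 61.5 ± 8.13 to 38.9 ± 1.58 CPM. The camera adjusted p of the list was 0.117 (0.0104 by rank, in a range from 0.0104 to 0.454 over the alternatives). The others were Krt7 (−0.60) and Upk3b (−0.47), whose calls were both lost without LPS replicate 1 or 2. Krt7 was also not called by DESeq2 on all libraries (−0.58; adjusted p = 0.0702). Between SGA360+LPS and LPS the median of the list was 0.04 (camera adjusted p = 0.828). There all 6 fibroblast markers lay above 0 (median 0.10; camera adjusted p = 0.118, and 0.0478 without SGA360+LPS replicate 2, in a range from 0.0478 to 0.717). Of the fibroblast markers 1 fell, the collagen gene Col3a1 (−0.41; camera adjusted p = 0.436 for the list). The B cell list had 1 rise, Spib (1.23), and the dendritic cell list 1, the integrin gene Itgax (0.60), which macrophages also express. The 4 T cell and 3 eosinophil markers tested had medians of −0.81 and 0.83 (camera adjusted p = 0.871 and 0.909), and NK cell and erythroid markers had no tested member. Of 7 mast cell markers 1 rose, Fcer1a (2.35), and 0 did when adjusted over the list alone. That call was lost with DESeq2 (adjusted p = 0.115, in a range from 0.0134 to 0.472) and without any 1 of the LPS or SGA360+LPS libraries, among others. Camp, an antimicrobial peptide gene in the neutrophil list, had no vehicle count and was at least 6.27-fold higher with LPS. The mesothelial, fibroblast, B cell, dendritic cell and neutrophil lists had 4, 1, 1, 1 and 1 of these calls when adjusted over the list alone as well.

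Of 7 LXR target genes 2 rose and 3 fell with LPS (2 and 3 adjusted over the list alone; camera adjusted p = 0.78), among them the cholesterol efflux genes Abca1 (0.86) and Abcg1 (−1.16). Of 9 fatty acid synthesis genes 4 fell and 5 had no call (4 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.324). Of 10 heat shock genes 5 rose and 5 had no call (5 adjusted over the list alone; camera adjusted p = 0.189, and 0.0446 by rank, in a range from 0.0446 to 0.506). The chaperone genes Hspa1a (1.38) and Hspa1b (1.27) were among them; they are near-identical copies and uncertain for that reason. Of 15 lysosome and autophagy genes 2 rose and 9 fell (camera adjusted p = 0.194), with Tfec at 2.67 and the proton pump subunit gene Atp6v0d2 at −1.40. Of 14 phagocytic and scavenger receptor genes 5 rose and 6 fell (5 and 6 adjusted over the list alone). Camera gave this list a downward adjusted p of 0.0683, in a range from 0.000562 to 0.749 over the alternatives. The scavenger receptor gene Marco rose by 1.64 while the Fc receptor gene Fcgr3 fell by 1.66. Fos fell by 1.89 and Junb rose by 1.69, both subunits of AP-1. Of 18 cell cycle genes 1 rose, 3 fell and 14 had no call (1 and 3 adjusted over the list alone; camera adjusted p = 0.759). The proliferation gene Mki67 rose by 0.77, while Rrm2 (−0.40), Mcm2 (−0.32) and Pcna (−0.29) fell. The 19 tested ribosomal protein genes had a median of 0.04 (camera adjusted p = 0.909).

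Vehicle replicate 1 held 59 genes at exactly 1 count, against 1064 to 1242 in the other 5 libraries. Depth lost to ribosomal RNA is argued against, since it kept 8261972 counts without Rn45s, more than the 7674245 of LPS replicate 1, which had 1116 genes at 1 count. Removal of low counts stays open. The mean chi-square per gene of the vehicle pair at 300 to 1000 counts was 7.37, against 2.26 for the LPS pair. Removal would not widen the spread at such counts, but it could hold beside whatever did, so this test cannot decide. A candidate explanation is few molecules copied many times: of 472 genes at 20 to 30 counts in vehicle replicate 2, 10.8% were at 0 in replicate 1, against 0 of 466 in the LPS pair and 19.2% predicted at 13.8 reads per molecule. The share of 10.8% lay below the prediction by more than 1.5 times and far above counting noise, so this stays open. From 10 to 1000 counts the mean chi-square of the vehicle pair was level (7.39, 7.39, 7.38 and 7.37), as a fixed number of reads per molecule would give. It was 8.86 and 12.81 in the bins above, and rose from 1.34 to 2.26 over 10 to 1000 counts in the LPS pair. These bins were no part of the planned test. No biological explanation was tested as both libraries are of 1 group.

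With SGA360, 18 of 19 chemokine genes lay below LPS alone, while 20 of 23 interferon-stimulated genes lay above. A lower share of macrophages is not excluded. In each of the 4 pairs of an SGA360+LPS and an LPS library the median of macrophage identity genes was above that of chemokines. The gap was as little as 0.167 (log2), within the spread over their members (0.272). That spread is between genes and is not the error of a median, so this bound cannot decide. The macrophage identity medians themselves were 0.01 to 0.07, above 0 in all 4 pairs, so no fall of these genes was seen. An equally weaker LPS response of all genes is argued against as the whole cause: beside a common loss of 8.98% of the LPS rise over 652 induced genes, 8 genes lay off it (adjusted p under 0.05 over these genes), the 7 lower ones and Rsad2 (0.39, against −0.13 from the common loss), and 20 and 24 did so without vehicle replicate 1 or 2. The 7 lower genes had already been called in the same libraries, so they are no separate support. The 652 genes were chosen for high values in the LPS libraries that are also the baseline here, so the common loss may be overstated. A smaller loss would bring Rsad2 nearer to it and put the 7 lower genes further off. A weaker response with a different loss for each gene was not tested. An effect of SGA360 on part of the LPS response stays open as a hypothesis. The interferon list lost its call with an estimated correlation (adjusted p = 0.456) and without LPS replicate 1 (0.063), in a range from 7.77e-17 to 0.456; its pair medians were 0.365 and 0.168 over LPS replicate 1, and 0.149 and 0.022 over LPS replicate 2.

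Over all genes, the LPS change and the SGA360 change had a negative covariance. Shared LPS libraries alone are argued against as its whole cause, since with separate LPS libraries in each comparison it was −0.0431 and −0.0458, where no sharing predicts 0. A partial reversal of the LPS change by SGA360 is a possible explanation that was not tested apart from a difference in handling between the groups.

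Lars2, a mitochondrial leucyl-tRNA synthetase gene, took 0.544% of counts in vehicle replicate 1 and 0.0319% to 0.0707% in the other libraries. Rn45s took 0.684% of counts in vehicle replicate 2, 0.682% and 0.220% in LPS replicates 1 and 2, and 0.604% and 0.294% in SGA360+LPS replicates 1 and 2.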
